A study of Homo sapiens with 47 samples.

How the data were processed

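Gene expression was measured on 47 Affymetrix Human Gene 1.0 ST arrays, each hybridised with material made from 100 ng of total RNA of a single sample. The samples came from 2 established human cell lines, LNCaP (prostate adenocarcinoma, 23 arrays) and U937 (leukemic monocyte lymphoma, 24 arrays). Cells had received the vehicle DMSO (0.1% by volume), phorbol 12-myristate 13-acetate (PMA, a phorbol ester, 100 nM) or bryostatin 1 (a macrocyclic lactone, 100 nM) for 1 h or 6 h. Both compounds bind the C1 domains of protein kinase C. Each of the 12 groups held 4 arrays, except LNCaP with DMSO at 1 h, which held 3.

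Per the labels the authors made the values with RMA, which corrects for background, normalises between arrays by quantiles and gives 1 value per transcript cluster, called a feature here. No version is stated, nor whether all arrays were normalised together. The scale is not stated either: the deposited values were read as log2 because they ran from 3.78 to 13.95 with near-equal medians (6.00 to 6.14) and interquartile ranges (2.61 to 3.02). They were used without further scaling. The authors report a one-way model with planned contrasts and Storey q-values, and a co-expression network, which was not analysed here.

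All 28869 features were tested and none was filtered out. The probe table used here listed 21062 of them, 19310 with exactly 1 gene symbol (18377 different symbols) and 1752 with several. The other 7807 were tested and counted but not named. A transcript can be measured by more than 1 feature (TNF by 3 with equal values), so counts of features are not counts of genes. Arrays hold no read depth, and their number limits the precision. Correlations between arrays of a group ranged from 0.987 to 0.997, and 87.5% of the variance over all arrays lay along 1 axis, which separated the cell lines.

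Group means were fitted with limma 3.58.1 in R 4.3.3 over all 47 arrays with 1 spread per feature moderated by eBayes. In 19 contrasts the compounds were compared with DMSO and with each other at each time in each line. The contrasts also held the change of the bryostatin minus PMA difference from 1 h to 6 h, the change in DMSO with time, and the difference between the lines in the PMA response (1 h and 6 h) and in the bryostatin minus PMA difference (6 h). A feature was called when its p, adjusted by Benjamini-Hochberg over all features of the contrast, was under 0.05, and counts at 2-fold or more were taken too. Values after ± are standard errors unless given as SD. Contrasts, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The array sets and the removal of arrays described below, the tests of explanations and the splits of arrays were chosen after results were seen, as was which of the genes that the rule allows were named.

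Up to 8 rises and 6 falls were named per contrast, the largest among called features with 1 symbol, 2-fold or more, a higher group mean above the median of all values, and (between 2 groups) no overlap of the arrays. Up to 4 called members of each gene list with the largest differences were added, and 18 genes of a fixed panel were allowed in any contrast.

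The 24 gene lists were immediate early transcription factors, feedback inhibitors of MAP kinase and NF-kB signalling, cytokines and chemokines, other NF-kB targets, extracellular proteolysis, EGF receptor ligands and receptors, androgen receptor targets, monocyte and macrophage markers, early myeloid markers, S phase, G2 and mitosis, cell cycle inhibitors and p53 targets, apoptosis regulators, protein kinase C and D isoforms with other C1 domain proteins, cholesterol synthesis, unfolded protein and amino acid stress, heat shock proteins, interferon response, ribosome biogenesis, actin and serum response factor (SRF) targets, LNCaP identity, U937 identity, fibroblast markers, and T and B lymphocyte markers. Each was tested against all other features with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Tests were repeated with an estimated correlation and with fry, which asks whether the members move on balance in 1 direction and does not compare them with other genes. A gene was represented by its feature with the highest mean.

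To follow early responses over time, features raised (or lowered) at 1 h by both compounds in a line, called and at least 2-fold (1.5-fold if fewer than 5 passed), formed a list. The score of an array was the mean over the list of its value minus the DMSO mean of that time. Scores at 6 h were compared by an exact 2-sided permutation test, 4 arrays against 4, with 70 arrangements and a smallest possible p of 0.0286. The arrangements ignored replicate numbers. Lists were made from 1 h arrays and tested on 6 h arrays. Features with a large change at 1 h by luck would move back toward 0 at 6 h with either compound.

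Replicate numbers 1 to 4 recur in every group, but the labels do not say whether equal numbers share a culture or a day, nor that replicates were separate cultures, so p-values measure the spread between these samples. After removing group means, arrays with equal numbers correlated with a median of 0.157 in LNCaP and 0.211 in U937. In 6 of the 14 contrasts between 2 groups of a line every such pair exceeded 0.1. The changes of the bryostatin minus PMA difference with time were not assessed for pairs. With the replicate block (the number within a line as a factor) 2 of these 6 counts moved by over 1.5 times: U937 bryostatin against DMSO at 1 h had 292 calls and U937 bryostatin against PMA at 6 h had 724. In LNCaP the second component (15.4% of the variance within groups) put replicates 1 and 2 on one side and 3 and 4 on the other in 23 of 23 arrays, and the sample descriptions code these sets differently. The reported LNCaP calls hold no term for these sets. As alternatives, LNCaP contrasts were fitted with the sets as a term and within each set.

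Alternatives were quantile normalisation or median centring of the deposited values, removal of dim features, features with 1 symbol only, eBayes with trend and robust settings, the methods' unmoderated planned contrasts with Benjamini-Hochberg or Storey adjustment, each cell line alone, array weights, the replicate block, and each array left out in turn. Chosen after seeing the data were the LNCaP sets as a block or apart and the removal of 4 arrays with a narrow value range. Retention scores were repeated with other fold limits, with either compound, and with the median. As both compounds share the DMSO arrays, correlations of their responses were set against simulated unchanged groups with shared controls and, where 4 controls allowed, against separate controls.

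The fit was tested on simulated data, with changes added to group means and independent normal noise of each feature's own spread. At 4 arrays against 3, 47 of 50 changes of 1.5-fold and 50 of 50 of 2-fold were recovered, with 8 false among 204 calls. At 4 against 4 (U937, 6 h), 45 of 50 and 48 of 50 were recovered, with 13 false among 206. Camera called 10 of 10 shifted lists and 0 of 30 others. These lists held random features with independent noise, so they tell nothing of false calls for lists with correlated members. For every contrast the count was also taken for other splits of the same arrays, all 35 or 100 drawn with a fixed seed.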

Results

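LNCaP and U937 cells were exposed to DMSO, PMA or bryostatin 1 for 1 h or 6 h, which made 12 groups of 4 arrays, except for 3 arrays of LNCaP with DMSO at 1 h. Each array gave log2 values of 28869 features. The title of the series names how long the changes of gene expression last as the difference of interest between the compounds, and the comparisons at 1 h and at 6 h address it. Differences are on the log2 scale, with standard errors from limma after ±, and "rose", "fell" and "called" refer to an adjusted p under 0.05. The genes named as called between 2 groups had no overlap between the arrays of these groups, except KLK3 between the compounds at 6 h in LNCaP and EGR1 between the DMSO arrays of U937.

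After 1 h of PMA, LNCaP cells raised immediate early transcription factors and feedback inhibitors of MAP kinase and NF-kB signalling. EGR1 rose by 6.26 ± 0.39 (76.8-fold), FOS by 5.99 ± 0.18 (63.5-fold), EGR3 by 4.29 ± 0.23 and FOSB by 3.77 ± 0.13, all of them transcription factors that respond to growth signals without new protein synthesis. ZFP36, which speeds the decay of cytokine mRNAs, rose by 4.21 ± 0.22, TNFAIP3, an inhibitor of NF-kB signalling, by 2.52 ± 0.25, and the MAP kinase phosphatases DUSP5 and DUSP1 by 2.26 ± 0.13 and 2.26 ± 0.12. The matricellular protein genes CCN1 (4.27 ± 0.10) and CCN2 (2.94 ± 0.10), the neutrophil chemokine gene CXCL8 (4.19 ± 0.38) and the stromelysin gene MMP10 (3.50 ± 0.18) rose too. TXNIP, a thioredoxin inhibitor, fell by 1.87 ± 0.34 and MYC fell by 0.67 ± 0.14. In total 1068 features were called, 728 higher and 340 lower (1239 and 1023 with array weights), and 179 rose and 15 fell by 2-fold or more.

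Of 24 immediate early factors measured, 18 rose, 1 fell and 5 did not pass (19 and 2 adjusted over the list alone; camera adjusted p = 9.1e-93). Of 27 feedback inhibitors 16 rose (17 adjusted over the list alone; adjusted p = 1.35e-39). Of 18 actin and SRF targets 10 rose (11; adjusted p = 1.68e-31), and of 20 interferon response genes 7 rose (8; adjusted p = 3.15e-11), among them OASL (1.28 ± 0.10) and RIGI (1.00 ± 0.14). These 4 lists were also called with an estimated correlation. Of 24 other NF-kB targets 8 rose (8 adjusted over the list alone), with REL at 1.34 ± 0.10, and adjusted p was 3.77e-09 and 0.0672 with an estimated correlation. Among 18 apoptosis regulators 3 rose (3; adjusted p = 0.000298, and adjusted p = 0.0874 with an estimated correlation), including PMAIP1, a BCL2 antagonist, by 1.98 ± 0.15.

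Bryostatin 1 also raised immediate early factors, feedback inhibitors and actin and SRF targets in LNCaP at 1 h. EGR1 rose by 6.00 ± 0.39, FOS by 5.62 ± 0.18, CCN1 by 3.88 ± 0.10, EGR3 by 3.59 ± 0.23, ZFP36 by 3.54 ± 0.22 and CXCL8 by 3.43 ± 0.38, and TXNIP fell by 1.92 ± 0.34. Of the lists, 18 immediate early factors rose and 1 fell (19 and 2 adjusted over the list alone; adjusted p = 7.87e-99), 15 feedback inhibitors rose (17; adjusted p = 1.28e-43) and 9 actin and SRF targets rose (10; adjusted p = 1.1e-42), called with an estimated correlation too. Of 20 interferon response genes 3 rose (4; adjusted p = 7.84e-06, called with an estimated correlation too). There were 646 called features, 475 higher and 171 lower, and 113 rises and 5 falls of 2-fold or more. Of the calls, 457 were higher with both compounds and 151 lower with both, where independent calls would share 12 and 2.01. Both compounds share the 3 DMSO arrays, which adds to these overlaps.

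Set against each other at 1 h in LNCaP, bryostatin and PMA differed in few features. All 42 called features were lower with bryostatin, 3 of them by 2-fold or more, and their genes included FOSB (-0.99 ± 0.12), the nuclear receptors NR4A3 (-0.95 ± 0.08) and NR4A1 (-0.49 ± 0.09), MMP10 (-1.06 ± 0.17) and PMAIP1 (-0.69 ± 0.14). PMAIP1 was not called without PMA replicate 1 (-0.66) or 3 (-0.67) or bryostatin replicate 1 (-0.61) or 3 (-0.63). Higher with bryostatin were 17 of 110 calls with array weights, 3 of 68 with the replicate block, 2 of 55 with the LNCaP array sets as a term, 2 of 45 with trend and robust settings, 1 of 46 after quantile normalisation and 1 of 29 without the arrays with a narrow range of values. Of the 24 immediate early factors 4 were called lower (13 adjusted over the list alone; camera adjusted p = 4.23e-26, called with an estimated correlation too), and of 20 interferon response genes 2 were (4; adjusted p = 2.43e-07, and adjusted p = 0.0124 with an estimated correlation). EGR1 was not called, at -0.26 with a 95% interval from -0.99 to 0.46, nor was CXCL8, at -0.76 with an interval from -1.47 to -0.05. Of 196 features changed at least 2-fold by either compound, 34 were called nearer to DMSO with bryostatin and 0 further, and for 173 the interval of the difference lay within 2-fold.

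Limits of the LNCaP comparisons at 1 h were these. Without bryostatin replicate 1 or without PMA replicate 3 the 42 calls became 26, and without PMA replicate 3 the 3 of 2-fold became 0. Within replicates 1 and 2 there were 780 (PMA), 482 (bryostatin) and 5 (bryostatin against PMA) calls, and within replicates 3 and 4 there were 159, 65 and 0. The second set had 1 DMSO array, taken to vary like the other groups. With the arrays of LNCaP alone MMP10 (-1.06, adjusted p = 0.0714) and NR4A1 (-0.49, adjusted p = 0.0528) kept their differences from PMA but were not called.

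**Figure D1:**
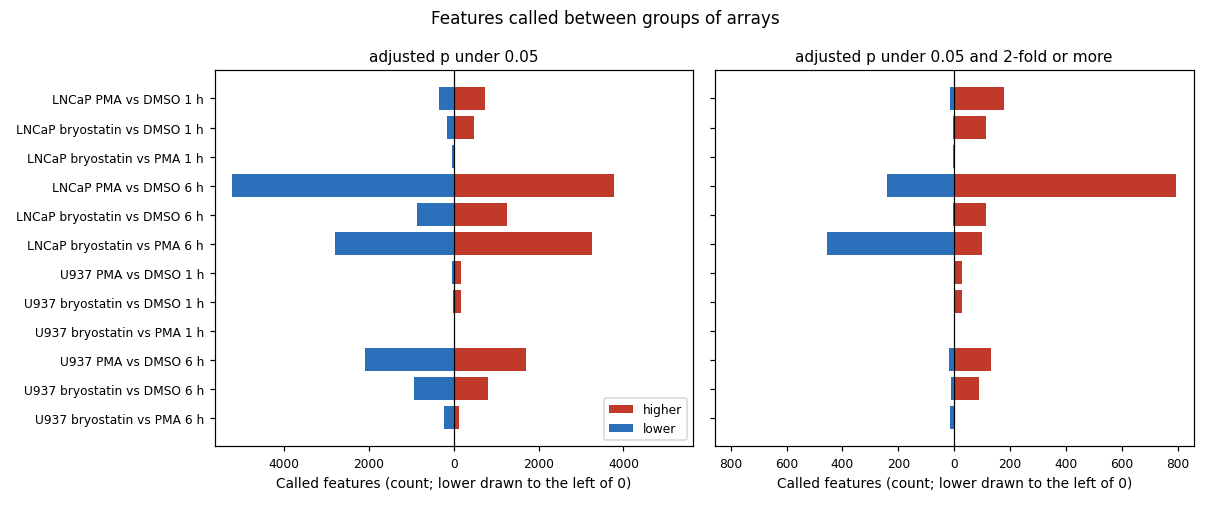
Number of features called in each comparison of a compound with DMSO and of bryostatin with PMA (limma, adjusted p under 0.05). Higher features are drawn to the right of 0 and lower features to the left. The right panel counts those that also differ 2-fold or more, and DMSO over time is not drawn. The contrasts of bryostatin with PMA hold 42 features at 1 h and 6055 at 6 h in LNCaP, and 0 and 361 in U937.

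After 6 h of PMA the LNCaP response held more called features than at 1 h. The tight junction gene CLDN1 rose by 5.85 ± 0.12 (57.6-fold), the integrin gene ITGA2 by 5.37 ± 0.11, the monocyte chemokine gene CCL2 by 5.34 ± 0.43, and the matrix metalloproteinase genes MMP10, MMP1 and MMP7 by 5.20 ± 0.17, 4.44 ± 0.29 and 4.17 ± 0.13. TNFAIP3 rose by 4.53 ± 0.23, PRKCA, which encodes protein kinase C alpha, by 2.92 ± 0.11, and CDKN2B, an inhibitor of cell cycle kinases, by 3.29 ± 0.13. TXNIP fell by 2.94 ± 0.31, LRIG1, which restrains receptor tyrosine kinases, fell by 2.12 ± 0.20, and the prostate transcription factor genes GRHL2 and HOXB13 fell by 1.97 ± 0.19 and 1.60 ± 0.14. In total 8996 features were called, 3771 higher and 5225 lower, and 793 rose and 239 fell by 2-fold or more.

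By list, 21 of 24 other NF-kB targets rose after 6 h of PMA in LNCaP (21 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.24e-21), and 18 of 27 feedback inhibitors rose and 1 fell (18 and 1; adjusted p = 3.11e-16). In the same contrast 14 of 21 proteolysis genes rose and 1 fell (14 and 1; adjusted p = 6.76e-15) and 14 of 18 actin and SRF targets rose (14 and 1 lower; adjusted p = 1.03e-17). Among stress and antiviral genes 13 of 16 genes of unfolded protein and amino acid stress rose (14; adjusted p = 5.59e-09) and 11 of 20 interferon response genes rose (11 and 1 lower; adjusted p = 6.08e-07). All 6 were called with an estimated correlation. Proliferation genes went the other way: 18 of 22 genes of G2 and mitosis fell (20 adjusted over the list alone; adjusted p = 9.49e-10, and adjusted p = 0.114 with an estimated correlation), as KIF20A (-1.67 ± 0.18) and BUB1B (-1.31 ± 0.12), and 17 of 22 S phase genes fell (19; adjusted p = 4.13e-06, and adjusted p = 0.217 with an estimated correlation), as MCM2 (-0.80 ± 0.08). Among 16 cell cycle inhibitors and p53 targets 9 rose and 2 fell (9 and 2; adjusted p = 0.000712, called with an estimated correlation). Of 25 cytokines and chemokines 11 rose (11; adjusted p = 3.6e-06, and adjusted p = 0.0593 with an estimated correlation), among them TNF by 2.74 ± 0.26 and CCL20 by 3.38 ± 0.19. Of 15 androgen receptor targets 8 fell and 4 rose (10 and 4; adjusted p = 0.118), with KLK2 and KLK3, prostate kallikreins, at -1.39 ± 0.14 and -1.11 ± 0.15. Of 23 monocyte and macrophage markers 5 rose (5; adjusted p = 0.0294, and adjusted p = 0.22 with an estimated correlation).

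After 6 h of bryostatin in LNCaP part of this response was present. CLDN1 rose by 3.57 ± 0.12 (11.9-fold), MMP10 by 3.56 ± 0.17, ITGA2 by 3.25 ± 0.11, MMP7 by 2.79 ± 0.13, CCL2 by 2.59 ± 0.43 and PRKCA by 1.55 ± 0.11. EGR1 (-0.01 ± 0.36), FOS (0.05 ± 0.17), CXCL8 (0.17 ± 0.35), TNF (-0.13 ± 0.26) and MYC (-0.05 ± 0.13) were not called. Of 21 proteolysis genes 11 rose (11 adjusted over the list alone; camera adjusted p = 3.02e-20), of 18 actin and SRF targets 8 rose (9; adjusted p = 5.42e-13), and of 16 cell cycle inhibitors and p53 targets 8 rose (9 rose and 1 fell; adjusted p = 1.85e-05), CDKN1A, the p21 gene, by 0.67 ± 0.16. These were called with an estimated correlation, unlike the other NF-kB targets (8 of 24 rose, 8 adjusted over the list alone; adjusted p = 5.17e-09, and adjusted p = 0.0874 with an estimated correlation) and S phase genes (8 of 22 fell, 13; adjusted p = 7.33e-10, and adjusted p = 0.11 with an estimated correlation). Of 23 monocyte and macrophage markers 5 rose (5; adjusted p = 0.000415, and adjusted p = 0.0746 with an estimated correlation). The contrast held 2104 calls, 1243 higher and 861 lower, and 113 rises and 4 falls of 2-fold or more.

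The direct comparison of the compounds at 6 h in LNCaP gave 6055 calls, 3251 higher and 2804 lower with bryostatin than with PMA, and 454 of the 555 differences of 2-fold or more were lower. Median centring turned the balance of all calls to 2734 higher and 2911 lower. EDN1, the endothelin gene, was at -4.20 ± 0.12, TNFAIP3 at -3.55 ± 0.23, CCN1 at -3.39 ± 0.09, CXCL8 at -3.22 ± 0.35, TNF at -2.87 ± 0.26, PLAU, the urokinase gene, at -2.37 ± 0.17, and PRKCA at -1.37 ± 0.11. Higher with bryostatin were ARRDC3 (2.28 ± 0.27), the transcription factor genes GATA2 (1.95 ± 0.13) and GRHL2 (1.81 ± 0.19), MYC (1.25 ± 0.13) and KLK3 (0.73 ± 0.15). Of 24 other NF-kB targets 19 were lower and 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 3.27e-22), of 27 feedback inhibitors 17 lower and 1 higher (18 and 2; adjusted p = 4.02e-19) and of 24 immediate early factors 15 lower and 1 higher (16 and 1; adjusted p = 6.16e-15), all called with an estimated correlation. Of 22 genes of G2 and mitosis 16 were higher (17; adjusted p = 2e-10, and adjusted p = 0.105 with an estimated correlation). Of 1043 features changed at least 2-fold by either compound, bryostatin was nearer to DMSO in 999, further in 7 and not called different in 37.

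Limits of the LNCaP comparisons at 6 h were these. Replicates 1 and 2 alone gave 7609 calls for PMA, 1165 for bryostatin and 5671 for bryostatin against PMA, and replicates 3 and 4 alone gave 3956, 169 and 690. PMA replicate 4 had the lowest median correlation with its own group of all arrays (0.990). Without this array the PMA contrast held 9337 calls and bryostatin against PMA held 6898. Its part in the lower counts of the second set was not tested.

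The difference between the compounds changed from 1 h to 6 h in LNCaP. This change was called for 3864 features, 2044 higher and 1820 lower, with 388 falls and 123 rises of 2-fold or more. Without the arrays with a narrow range of values the balance turned to 1731 higher and 1875 lower. EDN1 was at -3.88 ± 0.17, TNFAIP3 at -3.40 ± 0.33, CCN1 at -3.00 ± 0.13, TNF at -2.92 ± 0.37, CXCL8 at -2.46 ± 0.50 and EGR1 at -1.75 ± 0.51, while FOS (-0.19 ± 0.24) was not called. Of 27 feedback inhibitors 16 were lower and 2 higher (16 and 3 adjusted over the list alone; camera adjusted p = 4.1e-14) and of 24 other NF-kB targets 16 lower and 1 higher (19 and 1; adjusted p = 2.4e-17), both called with an estimated correlation. Among 24 immediate early factors 10 were lower and 4 higher (12 and 4; adjusted p = 0.00017, and adjusted p = 0.197 with an estimated correlation). Within replicates 1 and 2 there were 3062 calls and within replicates 3 and 4 there were 30. With all arrays but PMA 6 h replicate 4 there were 4964.

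Features raised at 1 h by both compounds were followed to 6 h. In LNCaP 111 features, of 79 named genes, had mean scores of 2.21 ± 0.101 (SD, 4 arrays) with PMA and 1.85 ± 0.0962 with bryostatin at 1 h. At 6 h the scores were 1.73 ± 0.261 (SD, 4 arrays) with PMA, 78.3% of the 1 h score, and 0.436 ± 0.0613 with bryostatin, 23.6% of it. The difference at 6 h was -1.30, and every bryostatin array was below every PMA array (exact permutation p = 0.0286, the smallest possible). It was -1.43 within replicates 1 and 2 and -1.17 within replicates 3 and 4. At 6 h 78 of the 111 were still at least 2-fold above DMSO and called with PMA and 18 with bryostatin. The change of bryostatin minus PMA from 1 h to 6 h was called lower for 69 of the 111 and higher for 6. The mean covers unlike courses with PMA. FOS went from 5.99 at 1 h to 0.61 at 6 h and EGR3 from 4.29 to 0.23, while CLDN1 went from 2.19 to 5.85 and EDN1 from 2.13 to 4.28. The 5 features lowered at 1 h by both, TXNIP among them, scored -1.54 ± 0.631 (SD) with PMA and -0.259 ± 0.174 with bryostatin at 6 h, a difference of 1.28 (exact permutation p = 0.0286), which was 1.66 and 0.904 within the sets. Without any 1 of the bryostatin arrays the exact p of this shorter list was 0.0571.

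**Figure D2:**
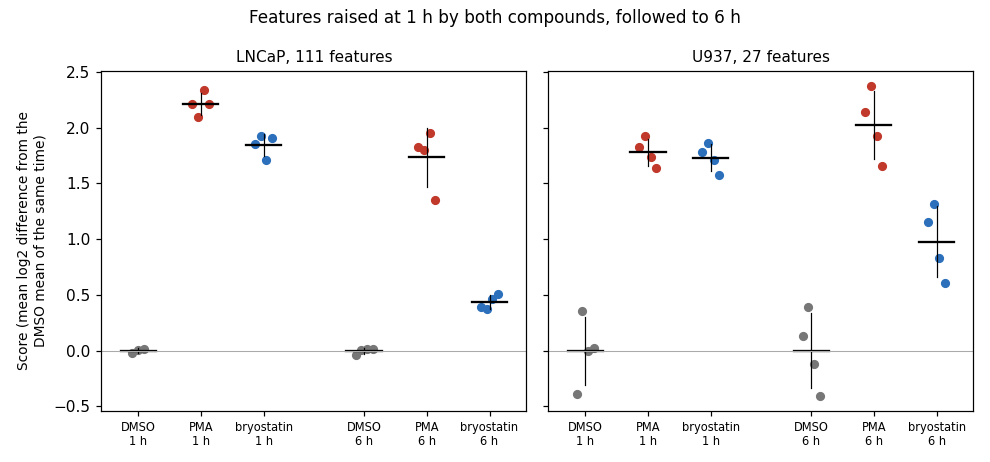
Score of each array (points), the mean log2 difference from the DMSO mean of the same time, over the features raised at 1 h by both compounds (111 in LNCaP, 27 in U937), with group means (wide lines) and SD (thin lines). From 1 h to 6 h the mean went from 1.85 to 0.436 with bryostatin and from 2.21 to 1.73 with PMA in LNCaP, and from 1.73 to 0.978 and from 1.78 to 2.02 in U937.

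In U937 cells 1 h of PMA raised early growth response factors, a growth factor and inflammatory mediators. EGR3 rose by 3.38 ± 0.21 (10.4-fold), EGR1 by 2.94 ± 0.36, HBEGF, which encodes a ligand of the EGF receptor, by 2.56 ± 0.29, CXCL8 by 2.53 ± 0.35, FOS by 1.90 ± 0.17, TNF by 1.89 ± 0.26 and ZFP36 by 1.86 ± 0.20. Bryostatin raised EGR3 by 3.30 ± 0.21, EGR1 by 2.95 ± 0.36, HBEGF by 2.51 ± 0.29, CXCL8 by 2.05 ± 0.35, FOS by 1.93 ± 0.17, TNF by 1.81 ± 0.26 and ZFP36 by 1.80 ± 0.20. Of 24 immediate early factors 13 rose with PMA (15 adjusted over the list alone; camera adjusted p = 4.77e-57) and 15 with bryostatin (16; adjusted p = 6.83e-64), and of 27 feedback inhibitors 7 rose with PMA (10; adjusted p = 3.07e-15) and 6 with bryostatin (11; adjusted p = 8.32e-20), all called with an estimated correlation. Of 25 cytokines 3 rose with either compound (4 with PMA and 3 with bryostatin adjusted over the list alone; adjusted p = 1.48e-05 and 9.2e-06, and adjusted p = 0.102 and 0.0964 with an estimated correlation). PMA gave 210 calls, 171 higher and 39 lower, with 28 rises and 0 falls of 2-fold or more, and bryostatin gave 190, 167 higher and 23 lower, with 29 and 0. The PMA split was 282 higher and 132 lower with the replicate block (414 calls), 191 and 127 with array weights, and 141 and 116 without the arrays with a narrow range of values.

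Between the compounds no feature was called in U937 at 1 h: limma gave 0 of 28869, with 1171 at an unadjusted p under 0.05, and the methods' unmoderated contrasts gave 0 too. EGR1 differed by 0.00 with a 95% interval from -0.73 to 0.73, FOS by 0.03 (-0.31 to 0.38), TNF by -0.08 (-0.61 to 0.44) and CXCL8 by -0.49 ± 0.35. Of 30 features changed at least 2-fold by either compound the interval lay within 2-fold for 29. Without PMA replicate 3 the PMA contrast held 139 calls, and without DMSO replicate 1, an array with a narrow range of values, the bryostatin contrast held 114. With the replicate block the bryostatin contrast held 292.

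After 6 h of PMA U937 cells raised members of the cytokine, feedback inhibitor and NF-kB target lists. TNF rose by 4.06 ± 0.26 (16.7-fold), the interferon-induced chemokine gene CXCL10 by 3.41 ± 0.32, CXCL8 by 3.37 ± 0.35, DCSTAMP, needed for the fusion of macrophages, by 3.20 ± 0.19, RGS1 by 2.92 ± 0.10, EGR1 by 2.84 ± 0.36 and IL1B by 2.66 ± 0.30. KBTBD7 fell by 1.75 ± 0.19, TXNIP fell by 1.37 ± 0.31 and P2RY2 fell by 1.28 ± 0.09. Of 27 feedback inhibitors 19 rose (20 adjusted over the list alone; camera adjusted p = 3.62e-23), of 24 other NF-kB targets 16 rose and 1 fell (16 and 1; adjusted p = 3.27e-15), and of 24 immediate early factors 15 rose (16; adjusted p = 2.44e-18). Of 25 cytokines 9 rose (12; adjusted p = 4.27e-12) and of 16 cell cycle inhibitors and p53 targets 9 rose (11; adjusted p = 2.67e-07), CDKN1A by 1.37 ± 0.16. Of 23 monocyte and macrophage markers 6 rose (7; adjusted p = 1.41e-05), the integrin gene ITGAX by 1.35 ± 0.10 and TLR2 by 1.28 ± 0.12, while CD14 was at 0.06 ± 0.07. The lists so far were called with an estimated correlation, and the 13 early myeloid markers were not (5 fell, 6 adjusted over the list alone; adjusted p = 0.00673, and adjusted p = 0.128 with an estimated correlation). There were 3781 calls, 1695 higher and 2086 lower, with 131 rises and 18 falls of 2-fold or more.

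After 6 h of bryostatin in U937 CXCL10 rose by 5.82 ± 0.32 (56.3-fold), TNFAIP3 by 3.48 ± 0.23, CXCL8 by 2.42 ± 0.35, TNFAIP6 by 2.36 ± 0.22, TNF by 2.28 ± 0.26, NFKBIA, an inhibitor of NF-kB, by 2.21 ± 0.16 and NFKB2 by 2.10 ± 0.14. EGR1 (0.10 ± 0.36), FOS (0.15 ± 0.17) and IL1B (0.77 ± 0.30) were not called. Of 24 other NF-kB targets 13 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 1.86e-26), and of 27 feedback inhibitors 13 rose (14 and 2 lower; adjusted p = 1.7e-14). Of 25 cytokines 7 rose (11; adjusted p = 5.45e-11), of 21 proteolysis genes 6 rose (7; adjusted p = 1.95e-06), including MMP9 by 1.04 ± 0.14, and of 23 monocyte and macrophage markers 5 rose (5; adjusted p = 9.51e-06), called with an estimated correlation too. Of 24 immediate early factors 5 rose (5; adjusted p = 5.53e-05, and adjusted p = 0.173 with an estimated correlation). There were 1740 calls, 802 higher and 938 lower, with 89 rises and 11 falls of 2-fold or more. The balance turned to 940 higher and 917 lower after quantile normalisation and to 699 and 518 without the arrays with a narrow range of values. Without bryostatin replicate 2, another array with a narrow range of values, there were 1063.

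Bryostatin and PMA at 6 h in U937 differed in 361 features, 123 higher and 238 lower with bryostatin, and in 3 higher and 16 lower by 2-fold or more. EGR1 was at -2.74 ± 0.36, EGR3 at -2.02 ± 0.21, IL1B at -1.89 ± 0.30, HBEGF at -1.80 ± 0.29, TNF at -1.78 ± 0.26 and CDKN1A at -0.67 ± 0.16. CDKN1A was not called without PMA replicate 1 (-0.66) or 2 (-0.56) or bryostatin replicate 1 (-0.64) or 4 (-0.56). CXCL10 was higher with bryostatin (2.41 ± 0.32), as were the RNA sensor gene IFIH1 (0.96 ± 0.15), SOD2 (0.73 ± 0.13), NFKB2 (0.71 ± 0.14) and FAS (0.56 ± 0.10). Of 24 immediate early factors 10 were lower (11 adjusted over the list alone; camera adjusted p = 3.47e-23, called with an estimated correlation), and of 27 feedback inhibitors 6 were lower (12 lower and 2 higher; adjusted p = 1.15e-08, and adjusted p = 0.121 with an estimated correlation). Of 24 other NF-kB targets 4 were higher and 1 lower (7 and 2; adjusted p = 0.0152, and adjusted p = 0.617 with an estimated correlation). CXCL8 was not called, at -0.95 with an interval from -1.66 to -0.24. Of 174 features changed at least 2-fold by either compound, bryostatin was nearer to DMSO in 45, further in 14 and not called different in 115, and 134 had an interval within 2-fold. Without PMA replicate 1 the 361 calls became 215 and without bryostatin replicate 3 they became 217, while the replicate block gave 724.

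In U937 the change of this difference from 1 h to 6 h was called for 56 features, 14 higher and 42 lower, with 2 and 11 of 2-fold or more. EGR1 was at -2.74 ± 0.51, EGR3 at -1.94 ± 0.30, TRIB1 at -1.16 ± 0.24, CXCL10 at 2.35 ± 0.45 and the complement gene C3 at 1.11 ± 0.25. Of 24 immediate early factors 4 were lower (11 adjusted over the list alone; camera adjusted p = 2.87e-16, called with an estimated correlation), and of 27 feedback inhibitors 2 were lower (5; adjusted p = 4.23e-07, and adjusted p = 0.232 with an estimated correlation). The count was 25 without bryostatin 1 h replicate 1, 32 without bryostatin 1 h replicate 2, 26 without PMA 1 h replicate 4, 27 without PMA 6 h replicate 1, 36 without PMA 6 h replicate 2, 28 without bryostatin 6 h replicate 3, and 14 with the arrays of U937 alone. With these arrays alone EGR1 (-2.74, adjusted p = 0.129) and CXCL10 (2.35, adjusted p = 0.0589) kept their values but were not called. TRIB1 was not called without bryostatin 1 h replicate 1 (-1.06) or 2 (-1.11), PMA 1 h replicate 4 (-0.95), PMA 6 h replicate 1 (-1.11) or 2 (-1.10) or bryostatin 6 h replicate 4 (-1.04). C3 was not called without bryostatin 1 h replicate 1 (1.07), 2 (1.084) or 4 (1.10), PMA 1 h replicate 2 (1.11), 3 (1.03) or 4 (1.13), PMA 6 h replicate 1 (1.06), 2 (1.105) or 4 (0.98) or bryostatin 6 h replicate 2 (1.07) or 3 (0.845), and in several other alternatives.

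The 27 features (19 named genes) raised at 1 h by both compounds in U937 scored 1.78 ± 0.122 (SD, 4 arrays) with PMA and 1.73 ± 0.122 with bryostatin at 1 h. At 6 h they scored 2.02 ± 0.305 (SD, 4 arrays) with PMA, 114% of the 1 h score, and 0.978 ± 0.318 with bryostatin, 56.5% of it, a difference of -1.05 (exact permutation p = 0.0286, the smallest possible). The permutation did not keep pairs of equal replicate number, although their scores moved together. For replicates 1 to 4 they were 2.14, 2.37, 1.93 and 1.66 with PMA and 1.16, 1.32, 0.83 and 0.61 with bryostatin. An exact test within 4 pairs cannot reach a p under 0.05. At least 2-fold above DMSO and called at 6 h were 21 with PMA and 10 with bryostatin. The list held 3 features of TNF and 3 of IER3, so the scores and percentages weight these genes more. From 1 h to 6 h of PMA TNF went from 1.89 to 4.06, and the highest IER3 feature from 2.21 to 3.40. EGR3 (3.38 to 2.39) and FOS (1.90 to 0.86) went the other way. Scores with each gene counted once were not computed. A list of 3 unnamed features lowered at least 1.5-fold by both at 1 h scored -0.525 ± 0.113 (SD) with PMA and -0.138 ± 0.151 with bryostatin at 6 h, a difference of 0.387 (exact permutation p = 0.0286). Without any 1 of the PMA arrays, or without bryostatin replicate 3 or 4, its exact p was 0.0571.

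Calls lasted longer with PMA in both lines by count. Of the features called higher at 1 h, 69.1% in LNCaP and 68.4% in U937 were also called higher at 6 h with PMA, against 29.5% and 32.3% with bryostatin. These shares were not tested against each other. Across features, and features are not independent replicates, the responses to both compounds correlated with r = 0.885 at 1 h and 0.719 at 6 h in LNCaP and with 0.726 and 0.834 in U937. Unchanged groups with shared controls gave 0.571, 0.502, 0.498 and 0.501 in simulations. With separate controls r was 0.62 (LNCaP, 6 h), 0.237 (U937, 1 h) and 0.655 (U937, 6 h), and 3 controls allowed no such value in LNCaP at 1 h. Without bryostatin 1 h replicate 2 the first r was 0.807.

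The lines differed in their response to PMA. At 1 h 537 features were called, 143 higher and 394 lower in U937 minus LNCaP, where higher also covers features that fell less in U937. FOS was at -4.09 ± 0.25, CCN1 at -4.19 ± 0.13, EGR1 at -3.32 ± 0.53, MMP10 at -3.47 ± 0.24 and KLF6 at -3.14 ± 0.21 (U937 minus LNCaP). For CCN1 and MMP10 this was close to the rise in LNCaP alone (4.27 and 3.50), and not an opposite change in U937. For EGR1 the levels themselves differed by 2.52 in DMSO and by -0.80 under PMA. RGS1 was at 1.73 ± 0.14, TNF at 1.69 ± 0.38 and CD69 at 1.44 ± 0.24. Of 24 immediate early factors 15 were lower and 3 higher (17 and 4 adjusted over the list alone; camera adjusted p = 1.28e-39) and of 18 actin and SRF targets 10 were lower (10; adjusted p = 6.55e-29), both called with an estimated correlation. At 6 h 5849 features were called, 3014 higher and 2835 lower (2565 and 2950 after median centring). CLDN1 was at -5.86 ± 0.17, ITGA2 at -5.37 ± 0.15, MMP10 at -5.21 ± 0.23 and PRKCA at -2.89 ± 0.15. These were close in size to the rises in LNCaP alone (5.85 for CLDN1 and 5.20 for MMP10), so they lay almost wholly in LNCaP. DCSTAMP was at 3.05 ± 0.26, IL1B at 2.30 ± 0.43 and TNF at 1.32 ± 0.37. Of 21 proteolysis genes 13 were lower and 3 higher (13 and 3; adjusted p = 4.2e-10, called with an estimated correlation), and of 22 genes of G2 and mitosis 17 were higher (19; adjusted p = 3.22e-11, and adjusted p = 0.159 with an estimated correlation). With the LNCaP array sets as a term the counts were 585 and 6137.

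At 6 h the difference between bryostatin and PMA itself differed between the lines in 3379 features, 1731 higher and 1648 lower in U937 minus LNCaP (3618, 1804 higher and 1814 lower, with the LNCaP array sets as a term). The balance also turned with dim features removed (1665 higher, 1824 lower), features of 1 symbol only (1431, 1503), array weights (2200, 2314) and the replicate block (2011, 2210). TNFAIP3 was at 4.38 ± 0.33, EDN1 at 4.23 ± 0.17, CCN1 at 3.32 ± 0.13, CXCL10 at 2.29 ± 0.45 and CXCL8 at 2.28 ± 0.50. ARRDC3 was at -2.29 ± 0.39, IL1B at -1.50 ± 0.43 (not called without U937 bryostatin replicate 4, -1.09) and MYC at -1.42 ± 0.18, while EGR1 (-0.73 ± 0.51) was not called. For EDN1, CCN1 and ARRDC3 the difference between the compounds in LNCaP alone, given above, was about as large with the opposite sign. Of 24 other NF-kB targets 17 were higher (18 adjusted over the list alone; camera adjusted p = 6.76e-26), of 27 feedback inhibitors 14 higher and 4 lower (15 and 5; adjusted p = 2.97e-11) and of 18 actin and SRF targets 9 higher (11; adjusted p = 1.17e-13), all called with an estimated correlation.

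**Figure D3:**
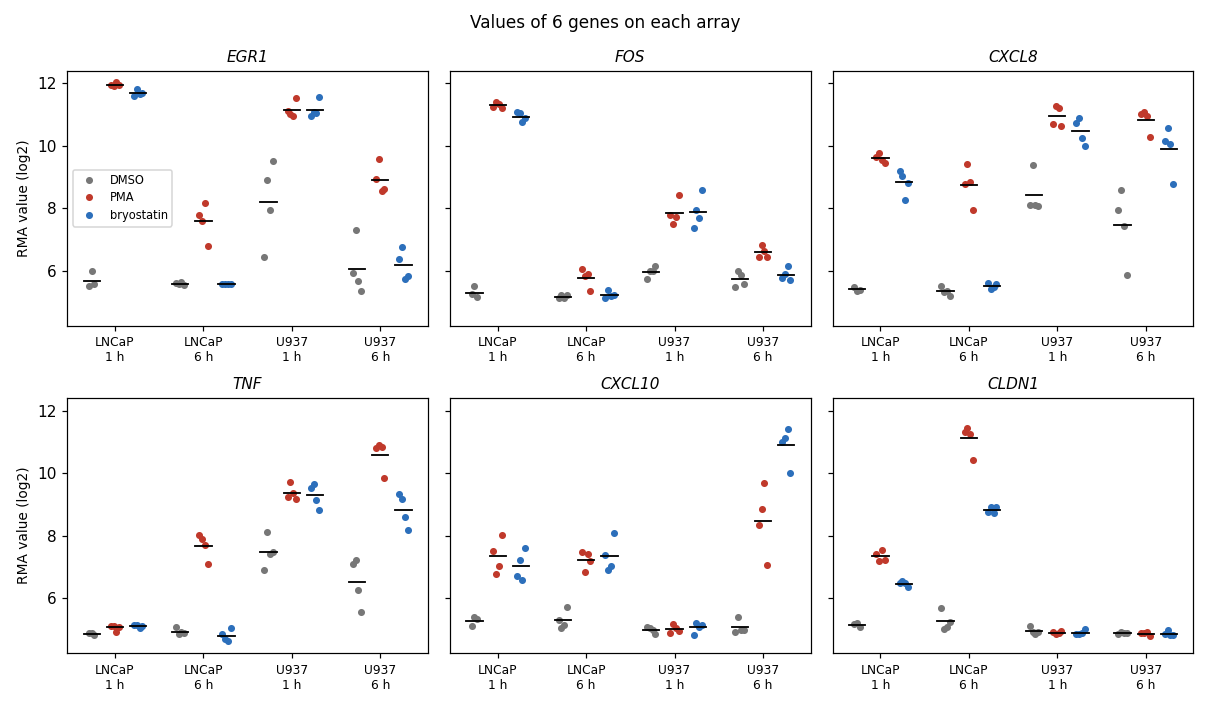
Log2 RMA values of 6 genes on each array (points) with group means (lines), by cell line and time, for DMSO, PMA and bryostatin 1; the genes were chosen after their values were seen. EGR1 in U937 falls with time in DMSO too, and CXCL10 at 6 h in U937 is the only one of the 6 with a higher mean in bryostatin than in PMA by over 1 on the log2 scale.

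Vehicle cells were compared between the times. In LNCaP limma called 0 features between DMSO at 6 h and at 1 h, with 561 at an unadjusted p under 0.05, and the methods' unmoderated contrasts gave 0 as well. Without DMSO 1 h replicate 3 or 6 h replicate 4 there was 1. In U937 7 features were called, 6 higher and 1 lower at 6 h, and the lower one was EGR1, at -2.13 ± 0.36. On the DMSO arrays EGR1 was at 6.46, 8.92, 7.96 and 9.51 at 1 h and at 5.94, 7.31, 5.69 and 5.36 at 6 h, so its differences from DMSO in U937 have unlike baselines at the times. Baselines of 3 lists differed as well by camera with the preset correlation: immediate early factors (median -0.158, adjusted p = 0.0012, and adjusted p = 0.765 with an estimated correlation) and early myeloid markers (adjusted p = 0.0225, and adjusted p = 0.765 with an estimated correlation) were lower at 6 h, and unfolded protein and amino acid stress was higher (adjusted p = 0.0356, and adjusted p = 0.765 with an estimated correlation). EGR1 was not called without DMSO 1 h replicate 2 (-1.90) or 4 (-1.70) or without DMSO 6 h replicate 3 (-2.00) or 4 (-1.90). The 7 became 2 without DMSO 1 h replicate 2 or 4 or 6 h replicate 3, and 3 without 1 h replicate 1 or 6 h replicate 4, and with the arrays of U937 alone there was 0. Within replicates 1 and 2 and within replicates 3 and 4 LNCaP had 0 calls each.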

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

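The tests of explanations and the array splits in this part were chosen after the results were seen, whereas the contrasts between times and between lines were planned.

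The difference between bryostatin and PMA changed from 1 h to 6 h by a test of the change itself, in 3864 features in LNCaP and in 56 in U937. In LNCaP EGR1 was at -1.75, CXCL8 at -2.46, TNF at -2.92 and CLDN1 at -1.40 (6 h minus 1 h), and in U937 EGR1 was at -2.74, TNF at -1.69 and CXCL10 at 2.35. The U937 count was 25 without bryostatin 1 h replicate 1, 26 without PMA 1 h replicate 4, 27 without PMA 6 h replicate 1, 28 without bryostatin 6 h replicate 3, 32 without bryostatin 1 h replicate 2 and 36 without PMA 6 h replicate 2. The call of TNF in U937 ended without PMA replicate 1 (-1.64), 3 (-1.70) or 4 (-1.62) or bryostatin replicate 1 (-1.61) or 2 (-1.58) at 1 h, and without PMA replicate 1 (-1.62), 2 (-1.59) or 3 (-1.62) or bryostatin replicate 3 (-1.62) or 4 (-1.48) at 6 h.

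The lines differed, by a test of the difference, in the response to PMA of 537 features at 1 h and 5849 at 6 h, and in the bryostatin minus PMA difference at 6 h of 3379. For U937 minus LNCaP at 1 h EGR1 was at -3.32, FOS at -4.09, CXCL10 at -2.04, CLDN1 at -2.24 and TNF at 1.69. The levels of EGR1 differed by 2.52 in DMSO and by -0.80 under PMA. At 6 h CLDN1 was at -5.86, CXCL10 at 1.49 and TNF at 1.32. The rise of CLDN1 with PMA in LNCaP alone was 5.85. For bryostatin minus PMA at 6 h CXCL8 was at 2.28, CXCL10 at 2.29, CLDN1 at 2.28 and TNF at 1.09. The last call ended without LNCaP PMA replicate 1 (0.97), 2 (1.02) or 3 (1.084), LNCaP bryostatin replicate 1 (1.11), 2 (1.05) or 3 (1.03), U937 bryostatin replicate 1 (0.92) or 2 (0.97), or U937 PMA replicate 4 (0.84) at 6 h.

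In 7 of 82 sets of 4 arrays 1 array stood apart from the other 3, where chance gives about 1 in 20. They were CXCL8 in U937 with DMSO at 1 h (9.38, replicate 2) and with PMA at 6 h (10.3, replicate 4), TNF in LNCaP with PMA at 1 h (4.92, replicate 3) and in U937 with PMA at 6 h (9.84, replicate 4), CXCL10 in U937 with DMSO at 6 h (5.40, replicate 2), CLDN1 in U937 with PMA at 6 h (4.80, replicate 4), and the score of the 5 features lowered at 1 h in LNCaP, with PMA at 6 h (-0.601 in replicate 4). Over all genes that could be named 186 of 2882 such sets stood apart (6.45%). PMA replicate 4 of U937 at 6 h stood apart in 3 of the 7. No explanation of these arrays was tested.

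The first pattern weighed was that genes raised at 1 h by both compounds were nearer to DMSO at 6 h with bryostatin than with PMA. The values argue against a bryostatin response that is weaker at both times alike: the ratio of bryostatin to PMA scores in LNCaP was 0.834 at 1 h (0.772 to 0.868 over the bryostatin arrays) and 0.252 at 6 h (0.217 to 0.294), and in U937 it was 0.972 (0.884 to 1.05) and 0.483 (0.301 to 0.65). The lists required a 2-fold rise with bryostatin at 1 h, which raises the 1 h ratios but not those at 6 h. Over features called and changed at least 2-fold by PMA at each time, the median ratio was 0.793 and 0.283 in LNCaP. In U937 it was 0.983 and 0.745. A difference between the sets of LNCaP arrays could not by itself make this pattern, because at 6 h each set held as many PMA as bryostatin arrays. The comparison within sets was therefore no test of it, and the smaller of the differences there was -1.17. Stronger induction of feedback inhibitor transcripts by bryostatin at 1 h was excluded in LNCaP (median difference -0.104, 21 of 27 below 0 and 0 above 0 at an unadjusted p under 0.05). In U937 it stays open (median 0.0223, 11 of 27 below 0), because the members went both ways. No such induction was seen there, with 0 above 0 at an unadjusted p under 0.05 and camera adjusted p = 0.83. A shorter signal from bryostatin may be the reason, a hypothesis that transcript levels at 2 times do not test at the level of protein kinase C.

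The second pattern was that 123 features, CXCL10 first among the named genes, were higher with bryostatin than with PMA in U937 at 6 h. A narrow value range of 1 bryostatin array was excluded as the whole reason, since without bryostatin replicate 2 112 features were called higher, 92 of them among the 123, and CXCL10 was at 2.33 (adjusted p = 6.02e-05). Further scaling of the deposited values did not remove the pattern, with 151 called higher after quantile normalisation and 103 after median centring. These scalings moved the median of a contrast by at most 0.0171 and 0.0261, as the values were already normalised. An effect of the original scaling was therefore not excluded. A broader NF-kB response with bryostatin stays open: 15 of 24 other NF-kB targets were above 0, with adjusted p = 0.0152 and adjusted p = 0.617 with an estimated correlation. These cannot be told apart from a list without a shift, as members went both ways.

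The third pattern was the smaller response of 15 immediate early factors to PMA at 1 h in U937. A higher level in U937 DMSO arrays was excluded for most of them: under PMA 9 of 15 were lower in U937 by 1 or more (median difference -1.60), while DMSO levels differed by a median of 0.457. For the other members it was not excluded. EGR1 was among them, at 2.52 in DMSO and -0.80 under PMA (U937 minus LNCaP), so much of its smaller response lay in the DMSO level. Some of the other members were not lower in U937 under PMA, with differences up to 0.19. A later response in U937 stays open. Of the 15, 4 were called lower at 6 h too, with a median difference of -0.0318 over members that went both ways, and no time between was measured. The gap at 6 h also closes where LNCaP falls back, so it cannot show a later response in U937. FOS with PMA went from 5.99 at 1 h to 0.61 at 6 h in LNCaP and from 1.90 to 0.86 in U937. The cell type itself, the difference that the design names, was not tested apart from other differences between the lines.

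Other splits of the same arrays were counted for each contrast. In LNCaP at 1 h no other split reached the real count for PMA (1068, 1 of 35 splits as large, highest other 673) or bryostatin (646, 1 of 35, 363). The same held for their difference (42, 1 of 35, 18, from the split by array set), with 5 and 0 calls within the sets. At 6 h no other split reached it for PMA (8996, 1 of 35, 5942), bryostatin (2104, 1 of 35, 196) or their difference (6055, 1 of 35, 4298). In U937 none did for PMA (210, 1 of 35, 128) and bryostatin (190, 1 of 35, 43) at 1 h, or for PMA (3781, 1 of 35, 763), bryostatin (1740, 1 of 35, 458) and their difference (361, 1 of 35, 126) at 6 h. A share of 1 of 35 is the smallest possible, and these splits ignore pairs of equal replicate number. Chance was therefore not excluded where the numbers pair the arrays. These contrasts are PMA at 1 h and bryostatin at 6 h in LNCaP, and bryostatin at 1 h and every comparison of treatments at 6 h in U937. For the others named here only the real split gave as many calls, but these splits do not exclude chance either. They ignore the array sets of LNCaP, and in U937 with PMA at 1 h 3 of 4 pairs correlated above 0.1.

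For the change with time 1 of 100 drawn splits was as large in LNCaP (3864, highest other 3848) and 4 of 100 in U937 (56, highest other 118). When labels were swapped only between arrays of equal replicate number, 5 of 100 splits were as large in LNCaP (highest other 4416) and 7 of 100 in U937 (highest other 72). Of these splits 13 in LNCaP and 11 in U937 kept the 6 h arrays grouped by compound, and so kept the difference at 6 h, which leaves little room for a share under 0.05. All 5 and all 7 were among them, and 0 of the remaining splits were as large in either line. The swaps therefore decide little.

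For the differences between the lines 1 of 100 drawn splits was as large for PMA at 1 h (537, highest other 259), 1 of 100 for PMA at 6 h (5849, highest other 5260) and 2 of 100 for bryostatin minus PMA at 6 h (3379, highest other 3481). With labels swapped only between arrays of equal replicate number, 10, 5 and 8 of 100 were as large (highest others 1079, 9199 and 4670). Of these splits 26, 13 and 13 kept the LNCaP labels or swapped all LNCaP arrays that had a partner, and so kept most of the LNCaP response, which leaves little room for a share under 0.05. They held 10, 4 and 8 of the splits that were as large, and of the remaining splits 0, 1 and 0 were. These swaps also decide little.

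The splits decide nothing where the real count was 0, since every split is then as large. In LNCaP DMSO (0 calls by limma, 561 at an unadjusted p under 0.05, 0 with the unmoderated contrasts) 35 of 35 splits gave as many, and the split by array set gave the highest other count, 34, which points to a structure of these arrays. In U937 DMSO (7 calls) 3 of 35 splits were as large, with 12 the highest other, so chance was not excluded. For bryostatin against PMA at 1 h in U937 (0 by limma, 1171 at an unadjusted p under 0.05, 0 with the unmoderated contrasts) 35 of 35 were as large, with 1 the highest other. In the 6 contrasts whose numbers pair the arrays the real split was compared with the 8 splits that part all pairs: 1 of 8 was as large, too few for a share under 0.05, and the highest others were 443 (LNCaP, PMA, 1 h), 1 (LNCaP, bryostatin, 6 h), 0 (U937, bryostatin, 1 h), 0 (U937, PMA, 6 h), 15 (U937, bryostatin, 6 h) and 0 (U937, bryostatin against PMA, 6 h; 724 calls with the replicate block).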

How the results depend on the processing

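The removal of arrays with a narrow value range and the LNCaP array sets as a term were chosen after the data were seen; the other alternatives were planned. Within 1.5 times of the reported number of calls stayed 19 of 19 contrasts under quantile normalisation, median centring, removal of dim features, eBayes with trend and robust settings, and the unmoderated contrasts with either adjustment, and 11 of 11 with the LNCaP array sets as a term. The scalings moved the median of all features by at most 0.0171 (quantile) and 0.0261 (centring). With only features of 1 gene symbol, so fewer features, calls were 687 for LNCaP PMA at 1 h (127 at 2-fold), 416 for LNCaP bryostatin at 1 h, 26 for LNCaP bryostatin against PMA at 1 h (1 at 2-fold), 2 for U937 DMSO over time and 348 for PMA at 1 h between the lines. Array weights gave 2262, 1058 and 110 for these 3 LNCaP contrasts, 1 for LNCaP DMSO, 318 for U937 PMA at 1 h, 650 for U937 bryostatin against PMA at 6 h, 87 for the U937 change with time and 1139 for PMA at 1 h between the lines. With the replicate block there were 68 (LNCaP bryostatin against PMA, 1 h), 414 and 292 (U937 PMA and bryostatin, 1 h), 724 (U937 bryostatin against PMA, 6 h), 168 (U937 change with time) and 22 (U937 DMSO). For array weights and the replicate block the cause was not tested. With the arrays of 1 line only, so fewer arrays, there were 26 (LNCaP bryostatin against PMA, 1 h), 14 (U937 change with time) and 0 (U937 DMSO, and 0 at 2-fold). Without the narrow arrays, so fewer arrays, there were 123 (U937 bryostatin, 1 h) and 3 (U937 DMSO). Leaving out 1 array in turn kept 168 of 188 counts and 102 of 109 at 2-fold within 1.5 times. Ranges where it did not were, for LNCaP bryostatin against PMA at 1 h, 26 (without bryostatin replicate 1 or PMA replicate 3) to 46, at 2-fold 0 (without PMA replicate 3) to 4; for LNCaP DMSO 0 to 1 (without 1 h replicate 3 or 6 h replicate 4); for U937 PMA at 1 h 139 (without PMA replicate 3) to 299; for U937 bryostatin 114 (without DMSO replicate 1) to 215 at 1 h and 1063 (without bryostatin replicate 2) to 1797 at 6 h. They were 215 (without PMA replicate 1; 217 without bryostatin replicate 3) to 366 for U937 bryostatin against PMA at 6 h and 25 to 75 for the U937 change with time. For U937 DMSO they were 2 to 7, and at 2-fold 0 (without 1 h replicate 2 or 6 h replicate 3 or 4) to 2 (without 6 h replicate 1 or 2 or 1 h replicate 3). The shorter retention lists ranged from 1.15 to 1.60 in LNCaP and from 0.344 to 0.454 in U937, with an exact p of 0.0571 in 10 of 32 such retention tests. The correlation of responses in LNCaP at 1 h ranged from 0.807 (without bryostatin replicate 2) to 0.901. All 4 retention scores kept direction and call in the other alternatives that gave a value; the 3-fold list was not run for the lowered features, as it held none. Of 456 list tests 179 were called, 66 with an estimated correlation, which replaces the preset one, 132 with fry, 168 with the mean of features and 184 with the replicate block. Of 188 gene values 169 were called, 153 stayed called in every alternative, 0 changed sign, and 2 of the others were called in at least 1. The 16 that lost the call in some alternative included TNF, EGR1 and CXCL10 for the U937 change with time. With the arrays of 1 line only EGR1 and CXCL10 for the U937 change with time, and MMP10 and NR4A1 for LNCaP bryostatin against PMA at 1 h, lost the call with their differences unchanged. Signal over background was not analysed here beyond the removal of dim features.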

Other observations

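This part holds planned tests of gene lists and values that the report did not use, and no test in it was chosen after the results were seen, while the lists and genes printed were.

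Some cholesterol synthesis genes rose in U937 within 1 h. Of 14 measured, 3 rose with PMA and 3 with bryostatin (8 and 8 adjusted over the list alone; camera adjusted p = 2.23e-09 and 2.95e-13, and adjusted p = 0.0834 and 0.0298 with an estimated correlation). STARD4, a cholesterol carrier, rose by 0.92 ± 0.13 with PMA and 0.91 ± 0.13 with bryostatin, HMGCS1, an enzyme of the pathway, by 0.72 ± 0.15 and 0.70 ± 0.15, and CYP51A1 by 0.60 ± 0.12 and 0.59 ± 0.12. With bryostatin CYP51A1 was not called without DMSO replicate 1 (0.50). HMGCS1 was not called without PMA replicate 1 (0.63) or 3 (0.66) or, with bryostatin, without bryostatin replicate 1 (0.67) or 3 (0.67). At 6 h in U937 3 rose and 1 fell with PMA (4 and 3 adjusted over the list alone; adjusted p = 0.277), and 1 rose and 3 fell with bryostatin (1 and 3; adjusted p = 0.22). Against PMA 1 was lower with bryostatin (4; median -0.171, adjusted p = 0.000431, and adjusted p = 0.426 with an estimated correlation). In LNCaP HMGCS1 rose at 6 h, by 1.70 ± 0.15 with PMA and 0.70 ± 0.15 with bryostatin, while of the list 2 rose and 2 fell with PMA (adjusted p = 0.141).

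Of 19 genes of protein kinase C and D isoforms and C1 domain proteins, 8 rose and 1 fell in LNCaP after 6 h of PMA (8 and 1 adjusted over the list alone; camera adjusted p = 0.00475, and adjusted p = 0.077 with an estimated correlation), and 7 were lower and 1 higher with bryostatin than with PMA (9 and 1; adjusted p = 0.000308, called with an estimated correlation). Of 18 ribosome biogenesis genes 4 fell in U937 after 6 h of bryostatin (5; adjusted p = 4.47e-07, and adjusted p = 0.139 with an estimated correlation). Of 11 EGF receptor ligands and receptors 2 rose in LNCaP after 1 h of PMA (2; adjusted p = 0.0078, and adjusted p = 0.0672 with an estimated correlation), and of 10 heat shock proteins 2 rose (2; adjusted p = 0.0213, and adjusted p = 0.288 with an estimated correlation). DNAJB1 was 1 of these, at 0.41 ± 0.11, and was not called without DMSO replicate 1 (0.40) or 3 (0.39) or PMA replicate 2 (0.38).

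Members of the LNCaP identity list moved both ways. Of 11 genes 4 rose and 6 fell after 6 h of PMA in LNCaP (4 and 6 adjusted over the list alone; adjusted p = 0.631), and of 14 genes of U937 identity 3 rose after 6 h of PMA in U937 (3; adjusted p = 0.0103, and adjusted p = 0.273 with an estimated correlation). Over the 19 contrasts camera called the 11 fibroblast markers in 0 (0 with an estimated correlation), with 1 member, FAP, higher in U937 at 6 h by 1.49 ± 0.21 with PMA and 0.93 ± 0.21 with bryostatin. It called the 11 T and B lymphocyte markers in 1, LNCaP with bryostatin at 1 h (1 rose, 1 adjusted over the list alone; adjusted p = 0.0452, and adjusted p = 0.432 with an estimated correlation). That member was CD4, which rose in LNCaP by 1.55 ± 0.15 and 1.64 ± 0.14 with PMA at 1 h and 6 h and by 1.30 ± 0.15 and 1.42 ± 0.14 with bryostatin.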
